A study of Mus musculus with 28 samples.

How the data were processed

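RNA was sequenced from single crypts of the small intestine of old wild-type mice, 1 library per crypt. Per the labels, about 150 crypts were screened by pyrosequencing of the promoters of 4 genes (Dkk1, Dkk2, Sfrp1 and Sfrp2), DNA and RNA having been taken from the same crypt, and crypts from the top 10% and the bottom 10% of the mean promoter methylation went into sequencing. Libraries of polyA RNA were made with a single-cell and low-input kit, per the labels. The 16 libraries labelled high and the 12 labelled low form the 2 groups, called high-methylation and low-methylation crypts here. The pyrosequencing values themselves were not analysed here. The labels name no mouse, sex, batch or sequencing day, so the crypts come from an unknown number of mice, and p-values measure only the spread between these crypts, which may be technical.

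The deposited files hold raw read counts per gene symbol, 1 file per crypt, each with 22310 gene rows and 5 closing rows that name no gene. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, aligned to the mm9 mouse genome with TopHat2 2.1.0 and Bowtie, and counted with HTSeq 0.11.2. The annotation, the strand setting and the read layout are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart, and no coordinates are given. HTSeq leaves out reads that align to several places, so members of gene families with near-identical copies, such as the Paneth cell defensins, have uncertain counts. The closing rows were used only to describe the libraries. The counts carry no molecular identifiers, so intervals and floors cover counting error only. No pair of libraries of 1 group had counts within sampling noise of each other (lowest chi-square per degree of freedom 19.4 among high-methylation and 29.8 among low-methylation crypts), so no library was counted as a repeat.

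Library totals ran from 7.56 to 22.9 M counts over genes (M for 1000000). A count of 0 allows up to 3 counts, which is a floor of 0.131 to 0.397 counts per 1000000 (CPM) in a single library, and of 0.0133 CPM over the high-methylation and 0.0146 CPM over the low-methylation libraries together.

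Differences between the groups were tested gene by gene with edgeR 4.0.16 in R 4.3.3, with TMM library factors, filterByExpr at its defaults, the quasi-likelihood test with a robust prior, and Benjamini-Hochberg adjustment over the 11310 genes kept by the filter, at a threshold of 0.05. Fold changes are given on the log2 scale, high minus low, with their standard error (SE). CPM values use TMM library sizes, while the floors use library totals. On simulated counts for these 11310 genes, drawn from the real means, dispersions and library sizes of the comparison of high with low crypts, with 50 genes changed at each fold, the test found 30% of the genes changed 1.5-fold, 66% of those changed 2-fold, 90% of those changed 4-fold and 94% of those changed 8-fold, and called 4 unchanged genes. The simulated genes varied independently and 144 were called in all, which eases the adjustment. Where few genes change, or genes and libraries vary together, changes of these sizes can be missed. A count of 0 genes therefore does not exclude large changes.

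The lists of genes (pathways and cell types), 43 in all, and the rule for the genes named in the text were fixed before the data were examined, as were the tests and most alternatives. A list was scored where at least 3 of its members passed the filter, which left 38. The score of a library is the mean log2 CPM of the members (prior count 2), and the difference of the group means was tested with a two-sided permutation test with 100000 resamples, Benjamini-Hochberg adjusted over the 38 lists. Intervals of 95% come from 10000 bootstrap resamples of the libraries. Members counted as higher or lower, and the median member of a list, use edgeR's log2 fold changes. That is a different scale from the score, so the 2 can differ in sign. Relabelled real libraries gave an unadjusted p under 0.05 in 5.13% of list tests over 100 relabellings. The test itself permutes labels, so this share checks the computation only and cannot cover crypts that share a mouse or batch. The 5 lists left out were the pyrosequenced genes and the mitochondrially encoded genes, each with 0 measured members, fibroblasts and smooth muscle with 1, enteric neurons and glia with 1, and erythroid cells with 2.

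Named genes are the 4 pyrosequenced genes; the genes past the threshold with the largest fold changes or, as no gene passed, the 5 with the smallest p in each direction at a mean of at least 10 CPM and a count in at least 50% of the libraries of the higher group; the 3 members with the smallest p of the Wnt inhibitor, Wnt target, iron, DNA methylation and stem cell lists; and the 1 with the smallest p of other lists. Lgr5 is said to be outside that rule where it appears. Other genes outside it also appear, among them those called only in an alternative or when adjusted over a list alone.

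Totals, detected genes, the share of counts in the 10 most abundant genes and the spread between crypts were compared with the same permutation test. Spread is the root mean square log2 distance of a library to the median of its group over the 1000 most variable genes. Alternatives were other library factors (RLE, upper quartile, totals alone, totals without the 50 most abundant genes), DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), no count filter or one of 5 CPM in 12 libraries, a non-robust prior, a replicate block, depth and detected genes as covariates, 5 surrogate variables (sva 3.50.0), thinning to 7.56 M counts, equal group sizes, and leaving out each library. For lists, camera with a preset correlation of 0.01 and with an estimated one, fry, z-scores and medians were added. Values without the 6 libraries under 10 M counts, the 2 with fewer than 11000 detected genes, or these 8, and Wnt lists without stem cell genes, were chosen after seeing the data. The count filter was run anew on each reduced set of libraries, so the measured members of a list could change there. Covariates on list scores were tested with Freedman-Lane permutation.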

Results

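Single small-intestinal crypts of old mice were compared by the methylation of 4 promoters of secreted Wnt antagonists: 16 crypts from the top and 12 from the bottom of the methylation range. An intestinal crypt is a gland kept up by a few stem cells at its base, so most of its epithelium descends from recent common ancestors. The series title places the comparison in the study of age-related, cancer-associated methylation drift. Counts over genes averaged 14.1 ± 4.83 M (SD, n = 16, where M is 1000000) in high-methylation crypts, with a range of 7.56 to 21.8 M, and 17.1 ± 3.03 M (SD, n = 12) in low-methylation crypts, with a range of 13.1 to 22.9 M. The permutation p for this difference was 0.0707. All 6 libraries under 10 M counts were high-methylation crypts (replicates 1, 2, 3, 4, 13 and 14). Detected genes numbered 12000 ± 1002 and 12450 ± 306, and the 2 libraries with fewer than 11000, at 10155 and 9034, were high replicates 7 and 9. The 10 most abundant genes held 8.87 ± 2.59% of the counts in high-methylation and 12.3 ± 4.69% in low-methylation crypts (permutation p = 0.0168).

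**Figure D1:**
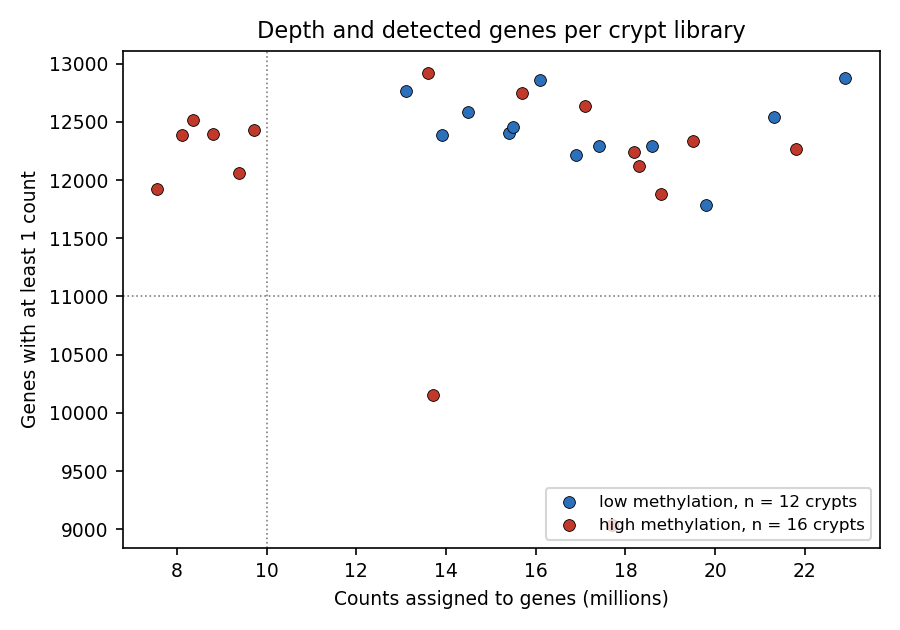
Counts assigned to genes in M (x axis) against the number of genes with at least 1 count (y axis), 1 point per crypt library, 16 high-methylation and 12 low-methylation; dotted lines mark 10 M counts and 11000 genes. The 6 libraries left of the vertical line and the 2 below the horizontal line are all high-methylation crypts.

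The genes whose promoters were used to choose the crypts were hardly transcribed in either group. Dkk1, Dkk2 and Sfrp2, secreted antagonists of Wnt signalling, had 0 counts in all 28 libraries, which allows up to 0.0133 CPM over the high-methylation and 0.0146 CPM over the low-methylation libraries. Sfrp1, of the same class, had 18 counts in 1 of 16 high-methylation crypts and 48 counts in 4 of 12 low-methylation crypts, at most 1.12 CPM in any library. The difference in the number of crypts with a count had a two-sided Fisher's exact p of 0.133. A difference in the transcription of Dkk1, Dkk2 or Sfrp2 was not detectable at this depth.

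Across all genes, the question was which transcripts separate crypts at opposite ends of the promoter methylation range. The smallest p among genes higher in high-methylation crypts belonged to Derl1, a component of endoplasmic reticulum quality control (132.6 ± 21.2 CPM in high, n = 16, and 103.6 ± 13.2 CPM in low, n = 12; log2 difference 0.36, SE 0.083), B4galt5 (29.6 ± 12.5 and 17.3 ± 3.63 CPM; 0.78, SE 0.19) and Dda1 (79.9 ± 10.4 and 64.9 ± 6.67 CPM; 0.30, SE 0.075). Pdx1, a transcription factor of the duodenum and pancreas, measured 18.4 ± 16 CPM in high-methylation and 2.41 ± 3.73 CPM in low-methylation crypts (log2 difference 2.92, SE 0.75). Clca3, a secreted goblet cell protein, measured 1353 ± 1083 and 457 ± 214 CPM (1.57, SE 0.40), with medians of 870.6 and 444.8 CPM. Clca3 was highest in high replicates 9, 15, 7, 6 and 11 (3550, 2970, 2960, 2230 and 2180 CPM). Among genes lower in high-methylation crypts, H2afj, a histone H2A variant, differed by -0.23 (SE 0.053; 277.6 ± 24.8 and 325.6 ± 24.5 CPM), the mitochondrial import factor Grpel2 by -0.34 (SE 0.091), ornithine aminotransferase Oat by -0.38 (SE 0.10), the folate enzyme Ggh by -0.85 (SE 0.24) and Nt5c3l by -0.46 (SE 0.13). None of these 10 genes passed the test.

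Of 11310 genes tested, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.648. At an unadjusted p under 0.05 there were 581 genes, 361 higher and 220 lower in high-methylation crypts, beside 566 if every p were uniform and a median of 347 over random splits of the same libraries. The biological coefficient of variation between crypts was 53.7%. DESeq2 called 4 genes (2210019I11Rik, H2afj, Pdx1 and Pla2g4c) and limma-voom called 0, with 1030 at an unadjusted p under 0.05. Without the 8 shallow or few-gene libraries, a setting chosen after seeing the data, edgeR called 21 genes, each at an adjusted p of 0.0493. Among them Parp9, Psmb8 and Psmb9, of the interferon list, and B2m, of the MHC class I list, were higher, and Cd1d1, Chrna10, Copz2, Grpel2, Kcne3, Ppat and Serf1 were lower.

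Wnt inhibitors, Wnt targets and the stem cell list were, with a myeloid list of 5 genes, the 4 lists with the smallest p. Of 12 measured Wnt inhibitors other than the pyrosequenced ones, 11 were lower in high-methylation crypts, and the list score differed by -0.70 (95% interval -1.08 to -0.35; permutation p = 0.00213, adjusted 0.0728). Its members with the smallest p were the ubiquitin ligase Znrf3 (62.9 ± 16.3 and 81.8 ± 16.2 CPM; log2 difference -0.38, SE 0.13), Axin2 (21.0 ± 7.16 and 27.2 ± 7.48 CPM; -0.37, SE 0.18) and Nkd1, which lay near the floor (0.378 ± 0.653 and 1.42 ± 1.10 CPM). These 3 are negative feedback regulators of the pathway that Wnt signalling itself induces. Of 28 measured genes of the Lgr5 stem cell list, 27 were lower, and its score differed by -0.64 (-0.999 to -0.30; permutation p = 0.0045, adjusted 0.0728). The sodium channel subunit Scn2b measured 54.5 ± 27.1 and 89.5 ± 23.5 CPM (-0.72, SE 0.23) and Olfm4, an abundant transcript of stem and progenitor cells, 2616 ± 1070 and 3644 ± 737 CPM (-0.48, SE 0.21). Of 21 measured Wnt target genes, 17 were lower (score difference -0.57, -0.93 to -0.24; permutation p = 0.00766, adjusted 0.0728), with Sox4 at 15.9 ± 5.58 and 23.2 ± 5.28 CPM (-0.55, SE 0.18), while Tcf7 pointed the other way at 2.46 ± 2.68 and 0.730 ± 0.695 CPM (1.74, SE 0.77).

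Lgr5, the receptor that names the stem cell list, lies outside the rule for named genes and was chosen after its values were seen. It measured 55.5 CPM on average in low-methylation crypts (n = 12, lowest 25.1 CPM) and 20.5 ± 24.7 CPM in high-methylation crypts (n = 16, median 5.11 CPM, highest 76.8 CPM), a log2 difference of -1.44 (SE 0.68; edgeR's unadjusted p = 0.044, Benjamini-Hochberg adjusted p = 0.943 over all genes). In 8 of 16 high-methylation crypts it was under 5.44 CPM, which is 10% of the low-methylation median, against 0 of 12 low-methylation crypts.

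**Figure D2:**
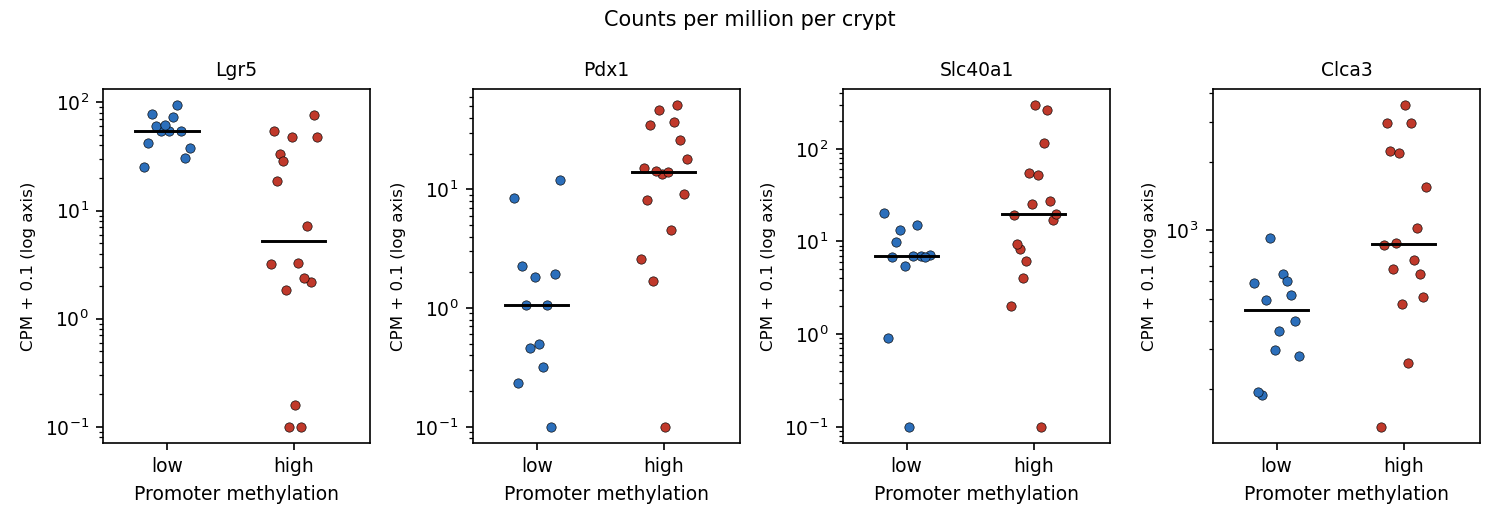
CPM plus 0.1 on a log axis for Lgr5, Pdx1, Slc40a1 and Clca3 in 12 low-methylation and 16 high-methylation crypts; points are crypts and bars are medians. Lgr5 spans 25.1 to 94.5 CPM in low-methylation crypts and 0 to 76.8 CPM in high-methylation crypts.

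Paneth cells, the antimicrobial secretory cells between the stem cells, gave the largest score difference of the lists. All 23 measured Paneth genes were lower in high-methylation crypts, and the score differed by -1.52 (-2.83 to -0.38; permutation p = 0.0283, adjusted 0.188). High replicate 11 stood apart, with a Paneth score of 0.0346 against 5.21 or more in the other 27 libraries, and without it the difference was -1.04. Gm15308, a defensin-family gene that shares sequence with its neighbours and is uncertain, measured 14.3 ± 16.2 and 51.6 ± 51.7 CPM. Secretory progenitor genes scored -0.30 (permutation p = 0.0346, adjusted 0.188), with 6 of 8 lower and 2 (Sox4 and Amica1) called when adjusted over the list alone, genes of regenerative or fetal-like epithelium -0.53 (permutation p = 0.0306, adjusted 0.188; 7 of 11 lower, with the tight junction gene Cldn4 at 10.7 ± 7.96 and 29.2 ± 19.9 CPM and 3 genes, Cldn4 lower and Ly6a and Ly6e higher, called when adjusted over the list alone), and Notch signalling genes -0.20 (permutation p = 0.0942, adjusted 0.325; Notch1 log2 difference -0.36, SE 0.20). The Notch score was -0.13 without high replicate 9, and -0.37 without the 6 shallow libraries, where it passed (adjusted permutation p = 0.0264). It did not pass without the 8 shallow or few-gene libraries. Over all libraries camera with an estimated correlation gave the Notch list an adjusted p of 0.49. The secretory progenitor score was -0.17 without low replicate 7 and -0.19 without low replicate 12 (unadjusted permutation p = 0.226 and 0.202). As the filter was rerun in these fits, the members of the list can differ, so the shifts cannot be credited to these crypts alone. Cycling genes differed little: G2 and M phase 0.10 (Cenpa log2 difference 0.30, SE 0.13) and S phase -0.11 (Ung -0.30, SE 0.15), with adjusted permutation p of 0.572 and 0.653.

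No list score passed after adjustment over the 38 lists, and 9 had an unadjusted permutation p under 0.05. Leaving out high replicate 10 brought Wnt inhibitors (-0.77) and the stem cell list (-0.69) to an adjusted permutation p of 0.0405, and leaving out high replicate 2 brought Wnt inhibitors (-0.78) to 0.0452. With depth and detected genes as covariates Wnt inhibitors passed (-0.65, adjusted permutation p = 0.0225). Wnt targets and the stem cell list did not. Without the 6 shallow libraries these lists all passed (in that order -0.88, -0.77 and -0.90, adjusted permutation p = 0.0155 each). They also passed with the few-gene libraries left out too (-0.77, -0.73 and -0.74, at 0.0169, 0.0217 and 0.0223). Leaving out these libraries was chosen after seeing the data. The 9 Wnt inhibitors that are not in the stem cell list scored -0.76 (permutation p = 0.00371), and the 12 such Wnt targets -0.25 (permutation p = 0.136), a split chosen after seeing the data. Fry called Wnt inhibitors, Wnt targets, the stem cell list and the myeloid list. Camera with a preset correlation called 17 lists, 6 lower and 11 higher in high-methylation crypts, and none of these calls held with an estimated correlation. The stem cell list, Wnt targets and Wnt inhibitors each had an adjusted p = 0.209 with an estimated correlation, and the Paneth list an adjusted p = 0.412 with an estimated correlation.

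**Figure D3:**
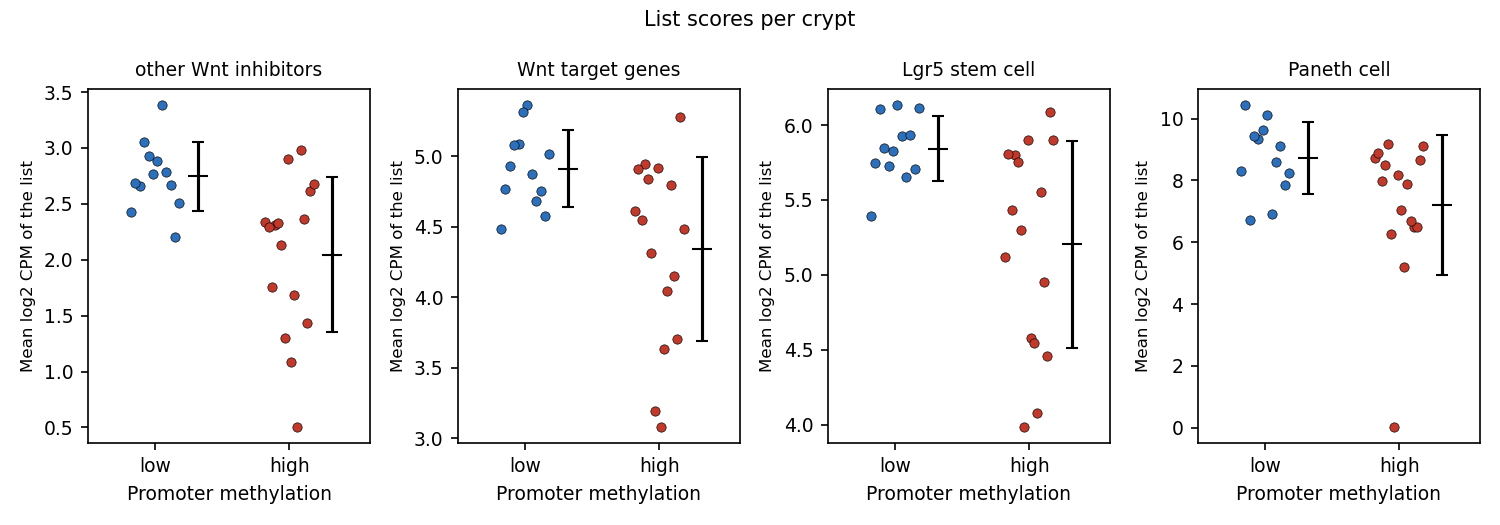
Mean log2 CPM of 4 gene lists in each of 12 low-methylation and 16 high-methylation crypts, where points are crypts, and the bars beside them are the mean and SD. The means are 2.75 and 2.05 for Wnt inhibitors, 4.91 and 4.34 for Wnt targets, 5.84 and 5.20 for the stem cell list and 8.72 and 7.21 for Paneth cells, in low-methylation and high-methylation crypts.

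Ferroportin (Slc40a1), which exports iron from cells, measured 57.5 ± 91.7 CPM in high-methylation crypts (n = 16, median 19.5 CPM) and 8.21 ± 5.67 CPM in low-methylation crypts (n = 12, median 6.86 CPM), a log2 difference of 2.81 (SE 0.80). Its mean in high-methylation crypts rested largely on high replicates 9, 5 and 14 (296, 263 and 116 CPM). The next highest crypt was high replicate 11 at 54.9 CPM. The ferritin heavy chain Fth1, which stores iron, measured 2844 ± 701 and 2241 ± 423 CPM (0.34, SE 0.12), and the metal importer Slc39a8 86.5 ± 28.6 and 121.3 ± 21.8 CPM (-0.49, SE 0.155). These 3 genes of 24 measured passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment when adjusted over the list alone (0.0381, 0.0474 and 0.0427), and 0 passed over all genes tested. The list as a whole scored -0.14 (-0.33 to 0.04, permutation p = 0.203, adjusted 0.429). In edgeR's log2 fold changes, a different scale from the score, 14 members were higher, 10 were lower and the median member was 0.07. Genes of iron-sulfur cluster and haem synthesis scored -0.03 (permutation p = 0.713, adjusted 0.848).

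The machinery of DNA methylation and demethylation gave no difference past the test. Its 26 measured genes divided into 13 higher and 13 lower, and the score differed by -0.04 (-0.23 to 0.11; permutation p = 0.762, adjusted 0.848). Those with the smallest p were the methyl-CpG reader Mbd2 (15.9 ± 5.99 and 12.9 ± 3.20 CPM; log2 difference 0.31, SE 0.18), Idh3a (0.15, SE 0.094) and Gadd45b (0.61, SE 0.46), and 0 of the 26 passed when adjusted over the list alone. Polycomb genes scored -0.24 (-0.56 to -0.0038; permutation p = 0.154, adjusted 0.416; Pcgf1 log2 difference 0.40, SE 0.19), with -0.11 without high replicate 9. Without the 6 shallow libraries, a setting chosen after seeing the data, the Polycomb list passed (-0.43, adjusted permutation p = 0.0261). It did not pass when the few-gene libraries were left out as well. Over all libraries camera with an estimated correlation gave the Polycomb list an adjusted p of 0.563.

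Interferon-response genes were all on the higher side in high-methylation crypts, 39 of 39, but with wide spread: the score differed by 0.38 (-0.08 to 0.88; permutation p = 0.181, adjusted 0.416), and by 0.22 without high replicate 15. Psmb10, an immunoproteasome subunit, measured 433.4 ± 89.5 and 350.3 ± 47.9 CPM (log2 difference 0.31, SE 0.096). All 13 measured MHC class I genes were higher as well (score 0.22, -0.05 to 0.50; permutation p = 0.186, adjusted 0.416), with B2m at 2424 ± 650 and 1994 ± 197 CPM (0.28, SE 0.11). Both lists passed with depth and detected genes as covariates (0.84 with an adjusted permutation p of 0.0225, and 0.56 with 0.00418), and without the 8 shallow or few-gene libraries (0.93 with 0.0217, and 0.66 with 0.00418). Under camera with an estimated correlation neither passed, the adjusted p being 0.287 for interferon and 0.209 for MHC class I. MHC class II genes scored 0.06 (adjusted permutation p = 0.848; H2-DMb1 log2 difference 0.20, SE 0.15) and NF-kB and acute-phase genes -0.34 (adjusted permutation p = 0.416; Duox2 -0.54, SE 0.32).

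Metabolic and stress lists showed small differences. Cholesterol synthesis scored 0.21 (0.0091 to 0.39; permutation p = 0.0531, adjusted 0.202), with 18 of 21 genes higher, 4 called when adjusted over the list alone and 0 over all genes. Insig1, which restrains the pathway, measured 67.3 ± 21.1 and 46.1 ± 10.2 CPM (0.55, SE 0.15). The unfolded protein response scored 0.06 (adjusted permutation p = 0.571), with 5 of 24 genes called when adjusted over the list alone, the chaperone partner Sdf2l1 first (0.38, SE 0.10). Oxidative phosphorylation scored 0.07 with 64 of 73 genes higher (adjusted permutation p = 0.488; Atp5g3 0.19, SE 0.065). The oxidative stress response scored 0.03 (Nqo1 0.31, SE 0.11), fatty acid oxidation and PPAR targets -0.0044 (Acaa1b 1.65, SE 0.90, near the floor), hypoxia -0.13 (Ldha 0.22, SE 0.078), ribosomal proteins -0.02 (Rps19 -0.12, SE 0.052), immediate early and heat shock genes -0.09 (Btg2 -0.37, SE 0.13) and BMP and TGF-beta response genes -0.07 (Id3 0.40, SE 0.14), each with an adjusted permutation p of 0.488 or more. Targets of p53 scored -0.33 (permutation p = 0.0434, adjusted 0.188) with 10 of 20 genes lower and a median member of 0.01, the proapoptotic Pmaip1 being higher (0.39, SE 0.16).

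Markers of position along the small intestine differed in some genes. Genes of the proximal end scored 0.43 (-0.12 to 1.00; permutation p = 0.164, adjusted 0.416), and 2 of 14, Pdx1 and Slc40a1, passed when adjusted over the list alone. Genes of the distal end scored -0.69 (-1.29 to -0.16; permutation p = 0.0445, adjusted 0.188), with 4 of 8 lower and a median member of 0.07. Without the 6 shallow libraries, a setting chosen after seeing the data, the distal list passed (-1.13, adjusted permutation p = 0.0155), and over all libraries camera with an estimated correlation gave it an adjusted p of 0.563. The distal list did not pass without the 8 shallow or few-gene libraries. Without low replicate 7 the proximal score was 0.26. The transcription factor Osr2 measured 13.1 ± 20.6 CPM in high-methylation and 46.0 ± 38.4 CPM in low-methylation crypts (log2 difference -1.82, SE 0.99).

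Lists of other cell types were scored to see what else the crypts held. Goblet cell genes scored -0.07 (adjusted permutation p = 0.797), 16 of 23 lower, although Clca3 passed when adjusted over that list alone. Enteroendocrine genes scored -0.81 (-1.81 to 0.25; adjusted permutation p = 0.416). The hormone gene Ghrl had medians of 0.22 CPM in high-methylation and 0.383 CPM in low-methylation crypts, and its log2 difference of 4.32 (SE 1.41) between means rested on high replicates 10, 6 and 8 (160, 76.3 and 27.9 CPM). Tuft cell genes scored 0.91 (-0.81 to 2.58; adjusted permutation p = 0.521; Matk 1.59, SE 0.81) and absorptive enterocyte genes 0.11 (adjusted permutation p = 0.848; Ada 0.46, SE 0.17). T cell genes scored 0.91 (-0.42 to 2.26; adjusted permutation p = 0.432; Cd3g 2.37, SE 1.09) and B and plasma cell genes -0.39 (adjusted permutation p = 0.488; Cd79b -0.28, SE 0.60). The 5 measured myeloid genes, 3 of them lower, scored -0.65 (-1.07 to -0.25; permutation p = 0.00656, adjusted 0.0728), with Lyz2 at 2.78 ± 7.84 and 19.1 ± 31.0 CPM (-2.75, SE 0.96), which passed when adjusted over that list alone. Fits without low replicate 1, 2, 4, 6, 8 or 9 gave a score between -0.36 and -0.43, but the filter was rerun in each. Low replicates 1 and 2 (scores of 2.04 and 2.20) lay below the low-methylation mean of 2.435, so their absence alone would not shrink the difference. The members of the list can differ between these fits, so the shifts cannot be credited to single crypts. Under camera with an estimated correlation the adjusted p of the myeloid list was 0.488. Lyz2 is a near copy of the abundant Paneth gene Lyz1, so its counts are uncertain. The 3 endothelial genes scored -0.07 (Lyve1 0.60, SE 0.44). The 4 Y-linked genes measured scored -0.28 (adjusted permutation p = 0.653, Uty -0.23, SE 0.21), Xist of the same list being too low to enter. The score was -0.049 without high replicate 5, -0.19 without high replicate 14 and -0.45 without low replicate 9. The score difference (mean log2 CPM) and the median member (edgeR's log2 fold change) differed in sign for 10 of the 38 lists, all with a score difference below 0. These were p53 targets, distal small intestine, iron, iron-sulfur and haem, hypoxia, immediate early, BMP and TGF-beta, fatty acid oxidation, B and plasma cells, and endothelium. The 2 measures lie on different scales, which alone could give such a difference in sign, and this was not tested.

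**Figure D4:**
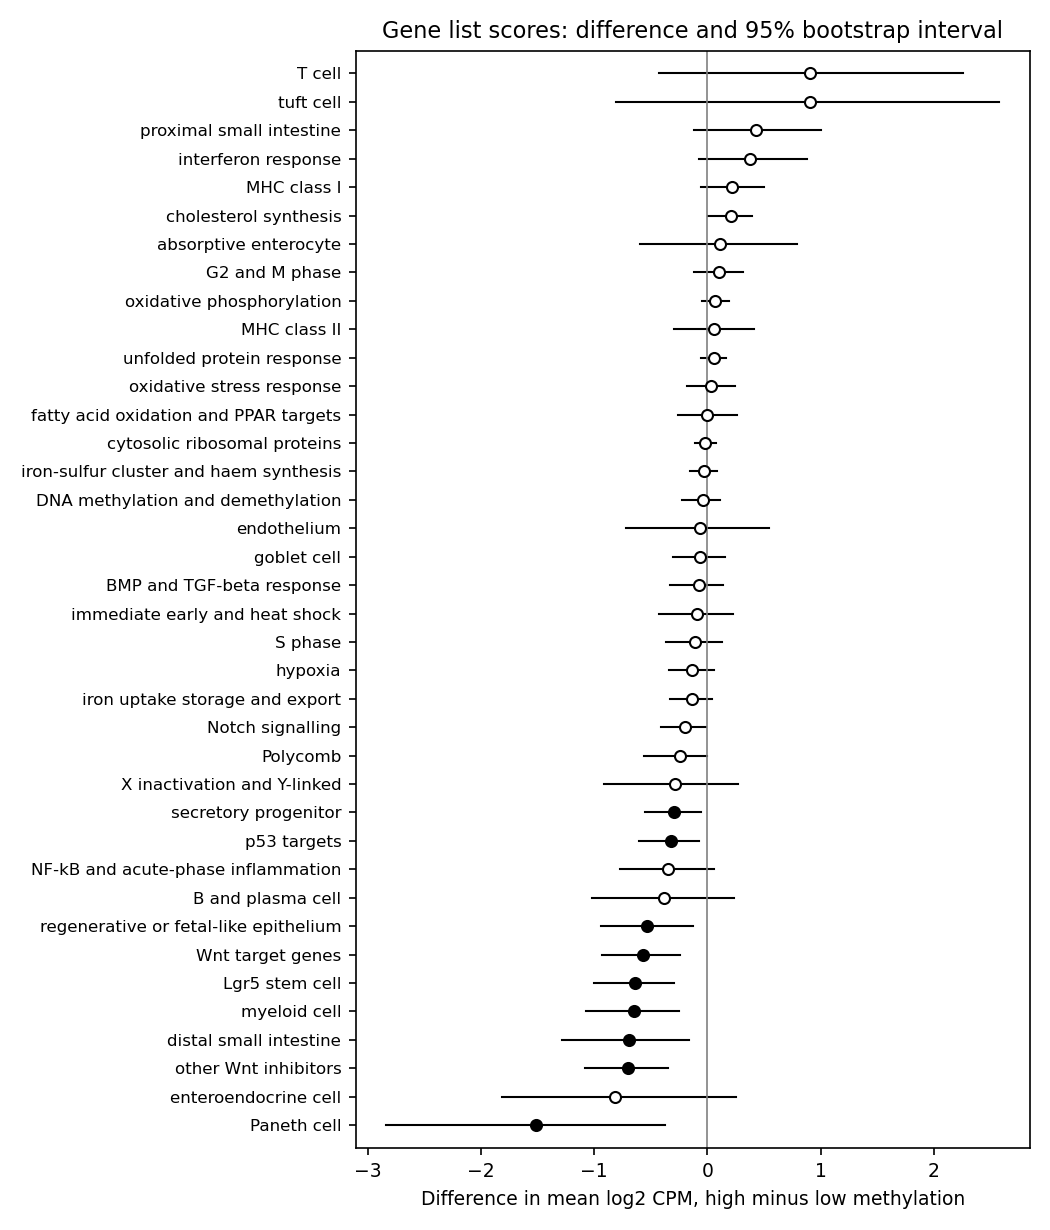
Difference in mean log2 CPM between 16 high-methylation and 12 low-methylation crypts (x axis) for 38 gene lists, where points are differences, lines are 95% bootstrap intervals, and filled points mark the 9 lists with an unadjusted permutation p under 0.05. The filled points lie between -1.52 for Paneth cells and -0.30 for secretory progenitors, and none passed after adjustment.

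The spread of crypts around their group did not differ past the test. The distance of a crypt to the median of its group was 2.101 ± 0.76 log2 units in high-methylation crypts (n = 16, range 1.38 to 4.05) and 1.65 ± 0.30 log2 units in low-methylation crypts (n = 12, range 1.18 to 2.18), a difference of 0.45 (0.09 to 0.86; permutation p = 0.0571), with medians of 1.81 and 1.69. High replicates 7 and 9, with the fewest detected genes, carried much of it: without both the difference was 0.18 (permutation p = 0.213), a setting chosen after seeing the data.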

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

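The tests that leave out the shallow or few-gene libraries were chosen only after the result was seen. The count of 0 genes by edgeR (581 at an unadjusted p under 0.05) stayed at 0 under RLE, upper-quartile and total-only factors, without the 50 most abundant genes in the library size, without a count filter, with a stricter one, with a non-robust prior, after thinning, with equal group sizes, under limma-voom, without the 2 libraries of few detected genes, and in all leave-one-out fits (lowest 0, highest 0). It was 4 with DESeq2, 2 with depth and detected genes as covariates, 4 with surrogate variables, 2 without the 6 shallow libraries and 21 without the 8 shallow or few-gene libraries. The count of lists, 0, stayed at 0 with RLE factors, z-scores, medians, the stricter filter, camera with an estimated correlation, and without the 2 libraries of few detected genes. It was 17 with camera at its preset correlation, 4 with fry, 3 with depth and detected genes as covariates, 8 without the 6 shallow libraries and 5 without the 8. Leaving out each library in turn gave 0 to 2 lists (1 without high replicate 2, 2 without high replicate 10). For none of these changes was the cause tested.

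With a replicate block the genes called stayed at 0 and the lists called went to 2, Wnt inhibitors (-0.75) and p53 targets (-0.42), each at an adjusted permutation p of 0.0186, against adjusted p over all settings of 0.000477 to 0.209 for Wnt inhibitors and 0.0186 to 0.851, the last with camera at an estimated correlation, for p53 targets. The list test with this block used replicate numbers 1 to 12 only, so high replicates 13 to 16 were left out of it. The labels do not say that shared numbers pair the samples, and the values did not show it. Deviations of the 12 same-numbered pairs correlated at -0.069 to 0.211, with 2 pairs over 0.1, and 1 high-methylation crypt correlated best with its own number. With so wide a spread between crypts, such correlations cannot exclude a shared mouse or batch.

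Of the 53 genes picked by the rule for named genes, 52 kept their direction under every alternative that kept them in the test (H2-DMb1 did not), as did 24 of the 38 lists. Leaving out 1 library moved 27 of the 38 list differences by over 1.5 times or to the other sign in at least 1 case. Some of these lists had a main difference so small that a slight shift suffices, such as fatty acid oxidation (-0.0044) and ribosomal proteins (-0.018). The filter was also rerun in each fit, so changed members can add to the shift. Over all alternatives the adjusted p ran from 3.57e-11 to 0.576 for the interferon list, 4.12e-06 to 0.576 for MHC class I and 1.86e-10 to 0.209 for the stem cell list. Oxidative stress genes, whose mean was 0.03, had a mean of -0.0079 on voom values while camera at its preset correlation called them higher. Sfrp1, removed by the filter, gave -1.56 (p = 0.197) with edgeR and -3.88 (p = 0.16) with DESeq2 when no filter was used. The difference in detected genes was -452.2 and, after thinning, -386.3; that in spread was 0.45 and ran from 0.16 to 0.44 in its alternatives. No library was under 1/3 of the median total of 15.9 M, so the planned settings without such libraries leave out nothing and were not run. Low depth limits the 6 libraries under 10 M counts, all high-methylation crypts, and no low-methylation crypt was that shallow.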

Other observations

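Of the tests that follow, both of Lgr5 on shallow or few-gene libraries and that on fewer stem cells, those without the 8 libraries, and that of Slc40a1 on position were chosen only after the result was seen. The search over all genes was prompted by Lgr5, though its own result had not been seen.

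Pla2g4c, Retnlb and Gsdmc4, picked after their values were seen and tested as no group, were high in a few crypts. Pla2g4c reached 1070 CPM in high replicate 9, 366 in high replicate 15, 306 in high replicate 11 and 71.7 in high replicate 6, then 34 in high replicate 7, with a median of 3.56 CPM over all 28 libraries. The goblet cell gene Retnlb reached 111, 130, 65.6 and 62.0 CPM in the same 4 crypts, with a median of 0.787 CPM. Gsdmc4, a gasdermin with close paralogs whose counts are uncertain, reached 719, 597, 206 and 163 CPM in high replicates 9, 15, 11 and 6, 111 and 110 CPM in high replicates 7 and 8, and 173 CPM in low replicate 8, where Pla2g4c was 31.5 CPM and Retnlb 0.268 CPM.

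Y-linked genes were low in single crypts, also seen only in the values. In high replicate 5, Ddx3y was 3.39 CPM, Eif2s3y 8.31, Kdm5d 1.64 and Uty 2.49, which is 4.3%, 7.51%, 5.61% and 7.24% of their medians over the other 27 libraries, while Xist had 1 count there (0.0606 CPM). In that library 4 of 5642 other genes with a median of 15 to 150 CPM fell under 10% of it. High replicate 14 had 5 counts of Ddx3y (0.522 CPM) beside 93.1 CPM of Eif2s3y, and low replicate 9 had 7 counts of Eif2s3y (0.560 CPM) beside 76.5 CPM of Ddx3y.

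Lgr5 lay under 10% of its low-methylation median in 8 of 16 high-methylation and 0 of 12 low-methylation crypts, a gene and a limit chosen after the values were seen, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave it an adjusted p of 0.943. Shallow or few-gene libraries cannot be the whole source, as 3 such crypts outside them (high replicates 11, 12 and 16) held 0, 27 and 51 counts of Lgr5, but for the 5 crypts among the 8 shallow or few-gene libraries that source cannot be told apart, their share not differing past the test from the 3 of 8 elsewhere (two-sided Fisher's exact p = 0.619). Fewer stem cells in these crypts cannot be told apart: 0 of the 24 other stem cell genes at 10 CPM or more were that low in as many high-methylation crypts, the most being 4 (Gkn3), but Lgr5 was picked as the extreme gene of its list, so this count excludes nothing. Another candidate explanation is many genes switched off in single high-methylation crypts: among the 26 libraries of usual gene number, 8 genes were on in all low-methylation crypts and off in at least 4 high-methylation crypts (among them Lgr5, Bmp3, Cyp2e1 and Ghr), against 1 gene (Pdx1) the other way, and random splits gave as many with p = 0.013 (median 0, highest 14). This is a hypothesis, since Lgr5 prompted the search and is among the 8, some of the 8 are Paneth cell genes that move together, and the methylation of these genes was not analysed here. Fewer Paneth-zone cells and position along the small intestine were not tested for Lgr5 and stay open. High replicates 11, 12 and 16 had Paneth scores of 0.0346, 6.49 and 5.21 (low-methylation mean 8.72). Their Osr2 was 1.25, 0 and 0.374 CPM (low-methylation median 30.5 CPM). High replicates 1 and 7, also near-absent for Lgr5, had 74.9 and 40.2 CPM of Osr2 and Paneth scores of 8.71 and 7.90. The remaining near-absent crypts, high replicates 4, 9 and 14, had 7.96, 0 and 0 CPM of Osr2 and Paneth scores of 6.26, 7.03 and 6.69.

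The stem cell list scored -0.64 in high-methylation crypts. Shallow or few-gene libraries do not account for it, as the difference without the 8 libraries was -0.74 (SE 0.27, permutation p = 0.00293). With the Paneth score as a covariate it was -0.38 (SE 0.18, permutation p = 0.0494), and with the proximal and distal scores as covariates -0.48 (SE 0.22, permutation p = 0.0422). Both lie within 1 SE of 50% of the main difference, a margin set after these values were first seen (without it both would count against the 2 sources), so crypts torn off above their base, with fewer Paneth-zone cells, and position along the small intestine cannot be told apart from a lower stem cell programme. A difference tied to the promoter methylation itself stays open and was not tested, and neither was one between mice.

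Slc40a1 differed by 2.81 (log2) in edgeR and by 1.71 in mean log2 CPM (permutation p = 0.0806). Shallow or few-gene libraries do not account for it (2.79 without the 8, SE 0.69, edgeR's unadjusted p = 0.000641). Among the crypts left in that fit, high replicate 5 stood highest at 263 CPM, the next being high replicate 11 at 54.9 CPM. Macrophages, which also export iron, do not account for the difference either. With the summed level of 6 macrophage genes (1.72 ± 1.54 CPM in high-methylation and 4.00 ± 4.07 CPM in low-methylation crypts) as a covariate it was 2.18 (SE 1.02, permutation p = 0.0415). Position along the small intestine stays open as a candidate source: with Pdx1 and Osr2 as covariates the difference was 0.53 (SE 1.04, permutation p = 0.615), undecided by the same margin of 1 SE, without which it would count for this source. Within high-methylation crypts (n = 16) Slc40a1 went against Osr2 (Pearson r = -0.654, permutation p = 0.0034, adjusted 0.0102; Spearman rho = -0.707, permutation p = 0.00296, adjusted 0.00888, over 6 relations; r = -0.520 without the 2 crypts farthest from the median of Osr2), and within low-methylation crypts (n = 12) r was -0.392 (permutation p = 0.181, adjusted 0.271) and rho -0.476 (permutation p = 0.122, adjusted 0.146), r being -0.532 without the 2 farthest, while with Pdx1 r was 0.126 (permutation p = 0.618, adjusted 0.618) and rho 0.462 (permutation p = 0.0736, adjusted 0.11) in high-methylation crypts, r being 0.767 without the 2 farthest, and r 0.356 (permutation p = 0.268, adjusted 0.322) and rho 0.245 (permutation p = 0.448, adjusted 0.448) in low-methylation crypts, r being 0.499 without the 2 farthest. The labels give no position for any crypt, so whether high methylation was sampled more often from the duodenal end was not tested.

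Among 100 splits of the 28 libraries into groups of 16 and 12, the real one included, 100 gave at least the real 0 genes and the highest other gave 1; 100 gave at least the real 0 lists and the highest other gave 3. Every split gives at least 0, so this comparison could not have come out otherwise and cannot exclude chance for either count. At an unadjusted p under 0.05, 16 of 100 splits gave as many genes as the real 581 (median of the others 347, highest 1441), and 4 of 100 gave as many lists as the real 9 (highest other 10). For the 20 libraries left without the 8 shallow or few-gene ones, 2 of 100 splits gave as many genes as the real 21, the other one giving 91. A structure among these libraries beside the groups, or genes that vary together, could give such a split, and neither was tested. The real 5 lists were the most of any split, the highest other giving 4.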
